A study of Mus musculus with 4 samples.

How the data were processed

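RNA from 4 mouse lung tumour cell lines grown as spheroids was sequenced by the study's authors from 500 ng of total RNA with a stranded mRNA kit. Reads were handled with STAR 2.5.1b, Cufflinks and DESeq2 1.10.1 on mm9, per the submitters' processing notes. The read counter, its strand setting and the gene annotation are not given in the sources used here. The column headers of the deposited tables are those of a first-generation DESeq table, while the notes name DESeq2. There is 1 deposited table per mutant line, each comparing that line with WT over 22620 entries.

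The deposited signal values are mean normalised read counts per line, named base means by the authors, per the file headers. The deposited fold values equal the ratio of the mean of side B to that of side A, and the deposited log2 values are its logarithm, both checked on the values. The file headers name the sides only A and B, and side B was taken as WT as described below. The sign of the log2 values was turned here, so that a positive value means higher in the mutant. The deposited p-value and adjusted p-value columns are the authors' own test of each line against WT, and the adjusted values equal a Benjamini-Hochberg adjustment over every gene with a p-value. The tables hold no values per sample, and 0 columns of per-sample values were left unused.

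The mean of 2 libraries divided by 2 size factors can take only certain values, so the whole reads of each library were solved from the deposited means. The 2 smallest steps in the values gave the worth of 1 read in each library, and the reads followed from them. In each table and line all 22620 entries were solved, 2 of them with more than 1 solution for M2, with a largest error of 6.11e-10 normalised counts. Side B held the same reads in all 3 tables and was taken as WT, the line common to the 3 comparisons. Libraries 1 and 2 of a line were numbered here by falling size factor. The size factors recomputed from the recovered reads differed from the solved ones by at most 1.11e-15. The entry that names no gene held 0.00792 to 0.0135% of a library's reads and was left out. The 8 libraries held 27328349 to 29889723 reads. Intervals and floors set by reads cover counting error only.

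The count of genes in each comparison with WT is the authors' own, at an adjusted p under 0.05. The plan, fixed before the data were examined, kept this test unless whole counts per library were deposited. The tables hold normalised means, so the count test on the recovered reads was added after the data were seen. It used edgeR's quasi-likelihood test with TMM scaling on 13803 genes over all 8 libraries (4 residual degrees of freedom, common biological coefficient of variation 0.0492), with a 2-sided test and Benjamini-Hochberg adjustment. CPM, SDs, SEs and adjusted p-values printed for genes come from this fit. A fold against a line with no read is set against 3 reads over that line's 2 libraries.

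Differences between mutant lines were tested with a z test of the difference of the authors' log2 fold changes. The tables give no SE, so it was derived from the log2 fold change and its p-value, and the SE of a difference ignores the shared WT. Genes with no read in WT or in either line of a pair have no finite fold change and were left out of the z test. Overlaps of calls were set beside those of independent lists and beside 100 simulations of unchanged lines against the same WT. Of 57 gene lists fixed at the same time, 54 had a percentile. Each list's median, with genes at 0 in 1 line set at their bound, was placed among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries and is not a test across replicates. Lists were tested with limma's cameraPR and camera, with preset and with estimated correlations. With an estimated correlation camera rested on 4 residual degrees of freedom and had little power. A list that did not pass it is not shown to be unchanged. Chromosomes were taken from the GENCODE annotation of mm9 (not necessarily that of the authors), which matched 20807 of 22619 gene symbols (92%), over genes with a mean of at least 10 normalised counts.

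Genes were named by a rule fixed in advance. It took Dicer1, Kras and Trp53, the 6 largest rises and falls per comparison with a mean of at least 100 normalised counts, and up to 3 called members with the smallest adjusted p from each list with at least 3 called members. It also took the 6 largest rises and falls common to all 3 lines, and for each pair of lines the 4 largest differences among genes called in opposite directions whose difference passed the z test. Predicted genes and clone names were left out of the largest changes. Per comparison, a gene with no read in 1 line has an infinite fold and ranked ahead of all others, so that order is not one of size.

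On simulated counts for M1 against WT (12679 genes), the edgeR test recovered 88.1% of 67 genes changed 1.5-fold, 91% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 7.5% of calls false. Recovery of whole reads from simulated means was right for 99.9% of 3002 values. The difference test recovered 88% of the genes made to differ by 3 on the log2 scale among 14000, with 2.22% of calls false. Of simulated lists with no shift 7.0% fell outside the central 95%, and of lists shifted by 1 SD 100%. The shares for the difference test and for shifted lists hold only for a difference and a shift of these sizes. Alternatives covered other thresholds, expression filters, scaling, tests, set tests and each library left out in turn. The work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.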

Results

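Gene expression was measured by RNA sequencing in 4 mouse lung tumour cell lines, a wild-type line (WT) and the mutant lines M1, M2 and M3. The labels give all 4 lines an oncogenic Kras allele, loss of p53 and a floxed Dicer1 allele beside a wild-type one, while the study's design text sets a wild type against lines with mutated Dicer1. Dicer1 is the ribonuclease that makes mature microRNAs. The cells grew as spheroids for 48 hours before RNA isolation. The authors' deposited table for each mutant line holds mean normalised read counts for that line and for WT, and whole reads per library were solved from these means, giving 2 libraries per line. The 8 libraries held 27328349 to 29889723 reads each, in 14899 to 16092 genes, and the 10 most abundant genes took 4.29 to 5.19% of them. Below, expression is given as CPM (counts scaled to the library total), mean ± SD over the 2 libraries of a line, with edgeR's quasi-likelihood log2 fold change ± SE against WT and its Benjamini-Hochberg adjusted p (n = 2 libraries per line). Folds against a line without reads are set against 3 reads over the line and cover counting error only.

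Libraries of a line lay closer together than libraries of different lines. Principal component 1 of log2 CPM held 54.1% of the variance and set M1 and M2 against WT and M3, component 2 held 27.4%, and component 3 held 15.9%. Across genes, which are not independent replicates, over the 13803 genes of the edgeR fit, the correlation of log2 CPM was 0.9952 to 0.9972 between libraries of a line and 0.8808 to 0.9559 between lines (means over pairs of libraries). Nothing says whether the 2 libraries of a line came from separate cultures. The p-values of edgeR, and of camera on the recovered reads, thus measure only the spread between these libraries, which may be technical. The deposited p-values, and the z test derived from them, rest on a larger spread. The dispersion they imply at high counts was 30.4, 67.6 and 33.3 times that within lines for M1, M2 and M3. The spread between libraries of a line exceeded counting noise in each line. The mean chi-square per gene, over genes with at least 100 reads, was 5.68 in WT, 16.2 in M1, 1.55 in M2 and 3.83 in M3. EdgeR estimated each gene's dispersion over all lines together, so its SEs may be too small for M1 and too large for M2. Fitted on only the 4 libraries compared, edgeR called 9217 genes against WT in M1, 10445 in M2 and 9678 in M3. Over all libraries it called 10001, 9882 and 9163.

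**Figure D1:**
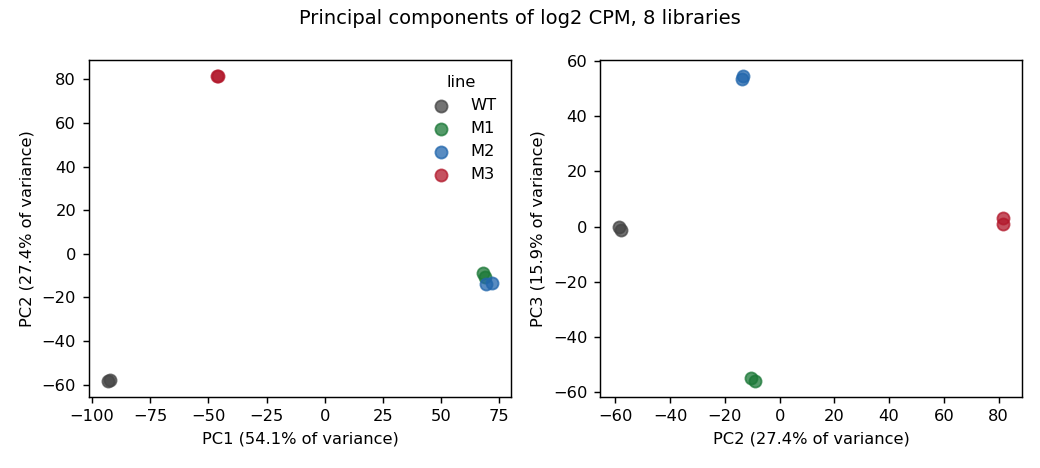
Principal components of log2 CPM in the 8 libraries, with 1 point per library and the share of variance on each axis. Libraries of a line lie together, component 1 (54.1%) separates M1 and M2 from WT and M3, and component 3 (15.9%) separates M1 from M2.

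Dicer1 itself (chromosome 12, 105925952 to 105990162, mm9) was expressed in all 4 lines. It stood at 40.6 ± 3.98 CPM in WT, 43 ± 0.748 in M1 (log2 fold change 0.08 ± 0.07, edgeR adjusted p = 0.335), 73 ± 0.0943 in M2 (0.85 ± 0.07, adjusted p = 5.52e-08) and 33.5 ± 1.11 in M3 (−0.28 ± 0.07, adjusted p = 0.00387). None of these differences passed in the authors' deposited table, whose adjusted p was 1.0 for M1, 0.215 for M2 and 0.891 for M3. Counts per gene cannot show the loss of an exon, so these values neither check nor contradict the labels. Kras, the oncogenic GTPase, stood at 104.5 ± 2.69 CPM in WT, 112 ± 10 in M1, 149.7 ± 2.74 in M2 and 94.4 ± 2.51 in M3. By edgeR the Kras difference passed in M2 (0.52 ± 0.06, adjusted p = 4.49e-06) and missed the threshold in M1 (adjusted p = 0.163) and M3 (0.0628). Without M1 library 1 the Kras difference in M1 passed (0.20), and without WT library 1 that of Dicer1 in M3 missed the threshold (−0.19). Reads of Trp53, the p53 gene, stood at 5.81 ± 0.491 CPM in WT and 5.35 ± 0.296, 5.72 ± 0.066 and 4.11 ± 0.151 in M1, M2 and M3, and passed by edgeR in M3 (−0.50 ± 0.13, adjusted p = 0.00385). Of 20 measured genes of the microRNA machinery, the authors' deposited tables called 0 in M1, 1 higher in M2 (Tnrc6a) and 1 lower in M3 (Zcchc11), both named after their values were seen, and 0, 0 and 1 passed adjusted over the list alone. With an estimated correlation that list had adjusted p = 0.587, 0.57 and 0.954.

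**Figure D2:**
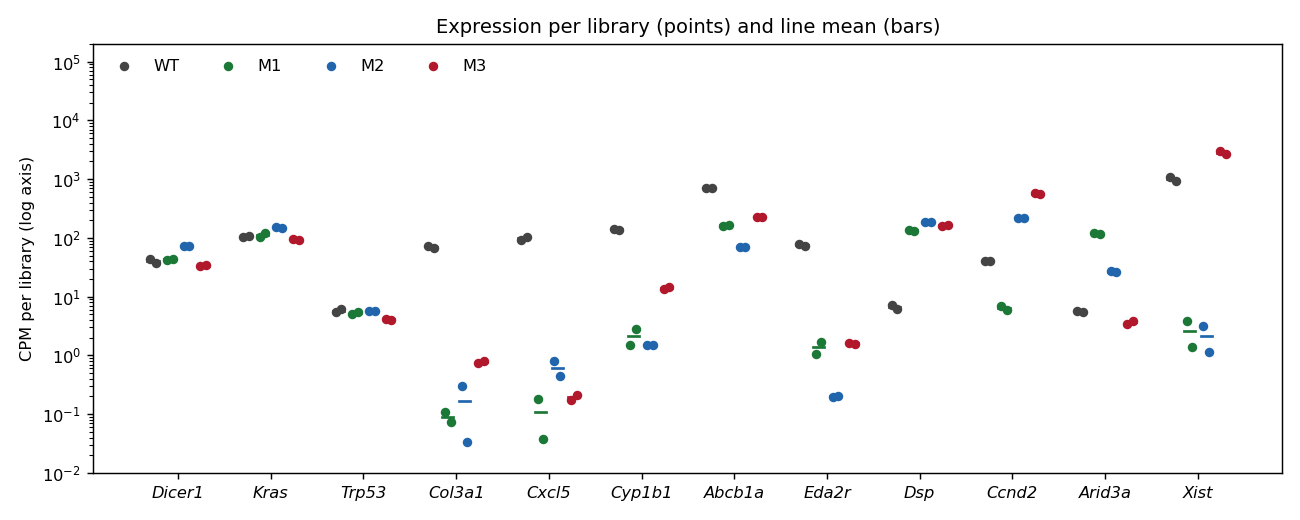
CPM per library on a log axis for 12 genes in the 4 lines, with points for the libraries and a bar for each line's mean. Col3a1, Cxcl5, Cyp1b1, Abcb1a and Eda2r lie lower and Dsp higher in M1, M2 and M3 than in WT, and Xist lies at 2.63 ± 1.77 CPM in M1 and 2833 ± 227 in M3.

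The first comparison asked how M1 differed from WT. In the authors' deposited table, 15 of 36 collagen and matrix genes, 8 of 23 mesenchymal genes and 7 of 25 drug-metabolism genes were lower in M1 (16, 9 and 8 adjusted over the list alone). By contrast 7 of 21 gut and embryonic endoderm genes were higher (9 adjusted over the list alone) in the authors' deposited table. No list passed camera with an estimated correlation in this comparison, where the smallest adjusted p was 0.587. On 4 residual degrees of freedom that test had little power, so this does not show that the lists were unchanged. Col3a1, a fibrillar collagen (chromosome 1, 45368383 to 45406551), fell from 69.6 ± 3.12 to 0.0908 ± 0.023 CPM (log2 fold change −9.51 ± 0.22, edgeR adjusted p = 2.76e-14), and Cyp1b1, a cytochrome P450, from 139 ± 4.89 to 2.17 ± 0.944 CPM (−6.01 ± 0.14, adjusted p = 1.94e-14). Apoc4 rose from 0.0684 ± 0.0464 to 35.9 ± 3.08 CPM (8.93 ± 0.23, edgeR adjusted p = 7.99e-14) and Apoc1 from 0.174 ± 0.0556 to 38 ± 4.13 CPM (7.74 ± 0.20, adjusted p = 1.14e-13). Apoc4 overlaps Apoc2 on chromosome 7, so its reads are uncertain. The authors' deposited table called 471 genes higher and 981 lower of 17367 tested, at an adjusted p under 0.05.

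Genes called higher in M1 also held Ttr, the thyroid hormone carrier transthyretin, which had no read in WT and 7.18 ± 0.395 CPM in M1, at least 138-fold higher. Hif3a, a hypoxia-inducible factor, rose by 8.32 ± 0.23 on the log2 scale (edgeR adjusted p = 1.95e-13). Dusp2, a phosphatase of MAP kinases, rose from 0.0524 ± 0.0265 to 15.7 ± 1.55 CPM and Ugt2b36, a glucuronosyltransferase, from 0.0347 ± 0.00132 to 9.77 ± 1.1 CPM. Some genes called lower had no read in either M1 library, so only a lower bound can be set on their falls. Genes with reads such as Col3a1 may have fallen further than some of them, though not further than Pik3r5 and Rnf150. Pik3r5, a regulatory subunit of PI3-kinase gamma, was at least 1535-fold lower than its 83.8 ± 2.2 CPM in WT, and Rnf150 at least 1491-fold lower than 81.4 ± 2.52. The glypican Gpc4 was at least 392-fold lower, the matrix protein Smoc1 at least 386-fold, cholecystokinin (Cck) at least 341-fold and the microtubule protein Map2 at least 328-fold.

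Of 36 tested collagen and matrix genes, 15 fell, 3 rose and 18 did not pass in M1 in the authors' deposited table, and 16 fell and 5 rose adjusted over the list alone (adjusted p = 0.827 with an estimated correlation). Besides Col3a1, nidogen 1 (Nid1), a basement membrane protein, fell from 163 ± 1.56 to 6.64 ± 0.644 CPM. The list's median log2 fold change of −1.52 in the authors' deposited table lay at percentile 0 of 10000 random lists matched on expression. Of 23 mesenchymal genes, 8 fell, 0 rose and 15 did not pass (9 fell and 1 rose adjusted over the list alone) in the authors' deposited table, with a median at percentile 0.020 (adjusted p = 0.587 with an estimated correlation). They include fibrillin 1 (Fbn1), which fell from 8.51 ± 0.545 to 0.0543 ± 0.0241 CPM, and the calcium-binding S100a4, which fell from 1102 ± 3.3 to 122 ± 9.28 CPM. Of 15 fibroblast genes 4 fell and 11 did not pass, 5 falling adjusted over the list alone, in the authors' deposited table (adjusted p = 0.587 with an estimated correlation). Of 15 basal and squamous genes 3 fell and 12 did not pass, 5 falling adjusted over the list alone, in the authors' deposited table (adjusted p = 0.587 with an estimated correlation). The squamous lineage factor Sox2 fell from 28.5 ± 0.945 to 3.9 ± 0.291 CPM.

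Of 49 growth factors and ligands, 10 fell, 0 rose and 39 did not pass in M1 in the authors' deposited table (12 fell and 2 rose adjusted over the list alone, adjusted p = 0.587 with an estimated correlation). Wnt4 went from 33.1 ± 1.19 to 1.17 ± 0.088 CPM, the activin subunit Inhba from 18.7 ± 1.12 to 1.16 ± 0.222 CPM and Bmp4 from 19.8 ± 0.98 to 1.79 ± 0.00416 CPM. Of 25 drug-metabolism genes, 7 fell, 0 rose and 18 did not pass in the authors' deposited table (8 fell and 2 rose adjusted over the list alone, adjusted p = 0.587 with an estimated correlation). Among them was the aldehyde dehydrogenase Aldh3a1, from 271 ± 19.9 to 16.8 ± 1.25 CPM. Among 23 TGF-beta and BMP targets 4 fell and 1 rose in the authors' deposited table, with 4 and 1 adjusted over the list alone (adjusted p = 0.587 with an estimated correlation). Tgfbi, a secreted adhesion protein, fell from 13.8 ± 0.698 to 0.109 ± 0.0482 CPM. Of 22 stem-cell associated genes 3 fell and 1 rose in the authors' deposited table, 4 and 1 adjusted over the list alone (adjusted p = 0.587 with an estimated correlation). Ly6a, the surface antigen Sca-1, fell from 257 ± 23.8 to 2.51 ± 0.334 CPM (−6.67 ± 0.10, edgeR adjusted p = 6.62e-16).

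Among genes higher in M1, 7 of 21 gut and embryonic endoderm genes rose, 1 fell and 13 did not pass in the authors' deposited table (9 rose and 1 fell adjusted over the list alone), with a median of 1.25 at percentile 100 (adjusted p = 0.587 with an estimated correlation). Apoa1, the main apolipoprotein of HDL, rose from 0.261 ± 0.0834 to 33.4 ± 3.03 CPM. The hepatic transcription factors Foxa3 and Hnf1a rose from 0.519 ± 0.0291 to 13.8 ± 1.17 CPM and from 0.36 ± 0.158 to 10.6 ± 0.596 CPM. Of 25 genes listed as targets of the let-7 microRNAs, 6 rose, 2 fell and 17 did not pass (7 rose and 2 fell adjusted over the list alone) in the authors' deposited table, with a median of 0.42 at percentile 99.5 (adjusted p = 0.587 with an estimated correlation). The DNA-binding protein Arid3a rose from 5.59 ± 0.0557 to 120 ± 3.4 CPM (4.42 ± 0.08, edgeR adjusted p = 2.80e-15), its relative Arid3b from 7.68 ± 0.245 to 49.8 ± 3.55 CPM, and the nuclear receptor Nr6a1 from 15.9 ± 0.095 to 152 ± 8.16 CPM. The lists of miR-200, miR-34 and miR-17-92 targets had medians inside the central 95% in M1 (percentiles 29.2, 4.79 and 45.3) in the authors' deposited table. Of their 16, 15 and 16 genes 0, 0 and 0 rose and 1, 0 and 1 fell in the authors' deposited table (0, 0 and 0 rose and 1, 0 and 1 fell adjusted over the list alone), with adjusted p = 0.858, 0.858 and 0.858 with an estimated correlation. Of 25 immediate-early genes 4 rose and 21 did not pass in the authors' deposited table, 4 rising adjusted over the list alone (adjusted p = 0.652 with an estimated correlation). The transcription factors Klf2 and Fosb rose by 3.78 ± 0.13 (edgeR adjusted p = 2.81e-12) and 2.34 ± 0.14 (8.14e-10) on the log2 scale. Of 24 cholesterol synthesis genes 0 passed in the authors' deposited table, also adjusted over the list alone. Their median of 0.48 in the authors' deposited table lay at percentile 99.9 (adjusted p = 0.587 with an estimated correlation), and 17 of 23 rose and 3 fell by edgeR.

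The cell-cycle lists had medians below 0 in M1, with no single member past the authors' threshold. Of 35 genes of the G1/S list and 34 of the G2/M list, 0 and 0 were called in the authors' deposited table, also adjusted over the list alone, with medians of −0.51 and −0.53 at percentiles 0.010 and 0 (adjusted p = 0.587 with an estimated correlation for each). By edgeR on the recovered reads 28 of 35 and 28 of 34 fell, and 2 of each list rose. Ribosomal protein genes had the same form, with 0 of 45 called in the authors' deposited table, also adjusted over the list alone, a median of −0.44 at percentile 0, and 35 falling and 1 rising by edgeR (adjusted p = 0.746 with an estimated correlation). Interferon-stimulated genes moved each way. Of 36, the authors' deposited table called 4 higher and 4 lower (7 and 4 adjusted over the list alone), with a median of 0.32 at percentile 99.7 (adjusted p = 0.587 with an estimated correlation). The protease Usp18 rose from 0.137 ± 0.0927 to 7.48 ± 1.55 CPM and the antiviral membrane protein Ifitm3 fell from 17.5 ± 1.23 to 0.40 ± 0.0907 CPM.

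Of the 54 lists with a percentile, 22 had medians outside the central 95% of random lists in M1, 8 above and 14 below. By chance 2.7 would, if the genes of a list were independent. Genes of some lists moved together (estimated correlation 0.6 for ribosomal proteins, but −0.0368 for mesenchymal genes) and lists share genes, so 2.7 may be too low. On the recovered reads edgeR called 10001 genes in M1 (4920 higher, 5081 lower, of 13803 tested), and 2540 when tested against a change of 2-fold. With Bonferroni adjustment 617 genes passed in M1 in the authors' deposited table. Without it, at an adjusted p under 0.05, 887 passed among genes with a mean of at least 100 normalised counts in the authors' deposited table. With a preset correlation of 0.05, the collagen, mesenchymal, gut and sex-linked lists passed in M1, but none did with an estimated correlation (adjusted p = 0.827, 0.587, 0.587 and 0.587). The median, mean and test of a list differed in sign for 10, 16 and 10 of 54 lists in M1, M2 and M3, none of them among the lists outside the central 95%.

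The second comparison set M2 against WT. In the authors' deposited table, 16 of 33 collagen and matrix genes, 9 of 23 mesenchymal genes and 13 of 50 growth factors and ligands were lower in M2 (17, 12 and 17 adjusted over the list alone), and 7 of 34 G2/M genes higher (9 adjusted over the list alone). No list passed camera with an estimated correlation in this comparison, where the smallest adjusted p was 0.504, again with little power. Nid1 fell from 163 ± 1.56 to 2.11 ± 0.114 CPM (log2 fold change −6.27 ± 0.09, edgeR adjusted p = 3.50e-16) and Krt7, a simple-epithelial keratin, from 238 ± 11.8 to 2.86 ± 0.506 CPM (−6.38 ± 0.10, 1.05e-15). Cyclin B2 (Ccnb2), a mitotic cyclin, rose from 51.2 ± 0.467 to 174 ± 0.918 CPM (1.77 ± 0.06, edgeR adjusted p = 1.05e-12), and the membrane protein Tm4sf1 from 4.72 ± 0.995 to 801 ± 19.2 CPM (7.40 ± 0.10, 2.11e-16). The authors' deposited table called 509 genes higher and 1224 lower of 17274 tested.

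Besides Tm4sf1, genes called higher in M2 held the phosphoglucomutase-like Pgm5 (7.90 ± 0.26, edgeR adjusted p = 1.57e-12) and Dusp2 (from 0.0524 ± 0.0265 to 11.8 ± 1.39 CPM). They also held Tmem252 (from 0.722 ± 0.266 to 155 ± 3.12 CPM), the cadherin Cdh16 (from 0.708 ± 0.0954 to 132 ± 4.28 CPM) and Spaca7, which had no read in WT and was at least 139.6-fold higher. Some genes called lower had no read in M2, with only lower bounds on their falls, and genes with reads such as Col3a1 may have fallen further. Those with no read included the receptor gene Cd200r2 (at least 328-fold lower), the imprinted gene necdin (Ndn, at least 324-fold), Trabd2b (at least 253-fold), the LIM-domain gene Pdlim1 (at least 226-fold), the phosphodiesterase Pde7b (at least 223-fold) and Fgf12 (at least 193-fold).

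Of 33 tested collagen and matrix genes, 16 fell, 3 rose and 14 did not pass in M2 (17 fell and 6 rose adjusted over the list alone) in the authors' deposited table, with a median of −1.11 at percentile 0 (adjusted p = 0.791 with an estimated correlation). Col3a1 fell to 0.166 ± 0.187 CPM and the fibulin Fbln1 from 11.9 ± 0.327 to 0.0831 ± 0.0698 CPM. Of 23 mesenchymal genes, 9 fell, 0 rose and 14 did not pass (12 fell adjusted over the list alone) in the authors' deposited table, with a median of −1.21 at percentile 0 (adjusted p = 0.504 with an estimated correlation). The transcription factors Twist2 and Prrx1 fell from 22.8 ± 0.455 to 2.04 ± 0.0744 CPM and from 59.5 ± 1.35 to 8.27 ± 0.34 CPM. Of 25 matrix proteases and their inhibitors, 6 fell, 3 rose and 16 did not pass (7 fell and 3 rose adjusted over the list alone) in the authors' deposited table (adjusted p = 0.504 with an estimated correlation). The inhibitor Timp3 fell from 95.7 ± 2.55 to 1.37 ± 0.0291 CPM and the plasminogen activator Plat rose from 68.3 ± 1.73 to 674 ± 3.43 CPM. Of 14 fibroblast genes 4 fell and 0 rose, with 4 falling adjusted over the list alone, in the authors' deposited table (adjusted p = 0.541 with an estimated correlation). Epithelial genes split, with 4 rising, 4 falling and 18 not passing of 26 in the authors' deposited table (4 and 5 adjusted over the list alone, adjusted p = 0.981 with an estimated correlation). The desmosomal protein desmoplakin (Dsp) rose from 6.62 ± 0.653 to 188 ± 1.78 CPM while the claudin Cldn4 fell from 37.8 ± 3.06 to 1.72 ± 0.0938 CPM.

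Of 50 growth factors and ligands, 13 fell, 0 rose and 37 did not pass in M2 (17 fell and 1 rose adjusted over the list alone) in the authors' deposited table, with a median of −0.66 at percentile 0 (adjusted p = 0.504 with an estimated correlation). Wnt4 fell to 1.44 ± 0.114 CPM, Wnt5a from 9.03 ± 0.369 to 0.267 ± 0.091 CPM and Gas6, a ligand of the TAM receptors, from 7.69 ± 0.514 to 0.0338 ± 0.0477 CPM. Of 25 drug-metabolism genes, 8 fell, 1 rose and 16 did not pass in the authors' deposited table, 8 falling adjusted over the list alone (adjusted p = 0.518 with an estimated correlation). Cyp1b1 fell to 1.49 ± 0.0039 CPM. Of 23 TGF-beta and BMP targets, 5 fell and 2 rose (8 and 2 adjusted over the list alone) in the authors' deposited table (adjusted p = 0.504 with an estimated correlation). The BMP antagonist chordin (Chrd) fell from 32.3 ± 1.36 to 1.2 ± 0.016 CPM and the plasminogen activator inhibitor Serpine1 rose from 179.5 ± 26.3 to 753 ± 3.54 CPM. Of 17 Wnt targets 4 fell and 1 rose, 4 and 1 adjusted over the list alone, in the authors' deposited table (adjusted p = 0.504 with an estimated correlation). Their median of −2.13 in the authors' deposited table lay at percentile 0.01, and 8 of 11 fell and 2 rose by edgeR. The ubiquitin ligase Rnf43 went against the list's median and rose from 10.7 ± 0.13 to 59.1 ± 1.33 CPM. Of 24 imprinted genes 4 fell and 2 rose in the authors' deposited table (5 and 2 adjusted over the list alone, adjusted p = 0.541 with an estimated correlation). Grb10, an adaptor of growth factor receptors, fell from 63.4 ± 3.94 to 0.134 ± 0.00178 CPM and Impact from 150 ± 2.69 to 3.61 ± 0.425 CPM.

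Of 34 genes of the G2/M list, 7 rose, 0 fell and 27 did not pass (9 rose adjusted over the list alone) in the authors' deposited table, with a median of 0.77 at percentile 100 (adjusted p = 0.504 with an estimated correlation). EdgeR called 31 of 34 higher and 0 lower. The spindle checkpoint kinase Bub1b rose from 51.5 ± 2.16 to 149 ± 3.4 CPM and the kinesin Kif23 from 63.8 ± 4.52 to 177 ± 3.59 CPM. Of 35 G1/S genes 2 rose, 2 adjusted over the list alone, in the authors' deposited table (adjusted p = 0.518 with an estimated correlation), and 23 rose and 2 fell by edgeR. Of 24 cholesterol synthesis genes 3 rose and 0 fell in the authors' deposited table, 3 rising adjusted over the list alone (adjusted p = 0.504 with an estimated correlation). They were the LDL receptor Ldlr (from 34 ± 2.79 to 116.5 ± 0.842 CPM), Sc4mol (from 51.9 ± 1.13 to 128 ± 0.774 CPM) and Dhcr24 (from 21.1 ± 0.0711 to 52.4 ± 0.322 CPM). Of 25 let-7 targets 4 rose and 3 fell in the authors' deposited table (5 and 3 adjusted over the list alone), with a median of 0.38 at percentile 99.8 (adjusted p = 0.559 with an estimated correlation). Cyclin D2 (Ccnd2), a driver of the G1 phase, rose from 40.2 ± 0.411 to 216 ± 0.837 CPM, while the RNA-binding protein Igf2bp3 fell from 16.1 ± 0.439 to 2.37 ± 0.252 CPM. The lists of miR-200, miR-34 and miR-17-92 targets had medians inside the central 95% in M2 (percentiles 88.2, 30.5 and 64.5) in the authors' deposited table. Of their 16, 15 and 16 genes 0, 0 and 2 rose and 1, 2 and 3 fell in the authors' deposited table (0, 0 and 3 rose and 1, 2 and 3 fell adjusted over the list alone), with adjusted p = 0.835, 0.791 and 0.881 with an estimated correlation.

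In M2, 19 of 54 lists had medians outside the central 95%, 6 above and 13 below, and with a preset correlation of 0.05 the mesenchymal, collagen, fibroblast, G2/M, drug-metabolism and sex-linked lists passed. None of these passed with an estimated correlation (adjusted p = 0.504, 0.791, 0.541, 0.504, 0.518 and 0.504). EdgeR called 9882 genes in M2 (4870 higher, 5012 lower), and 2320 against a change of 2-fold. With Bonferroni adjustment 769 passed in M2 in the authors' deposited table.

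The third comparison set M3 against WT. In the authors' deposited table, 11 of 31 NF-kB and inflammatory genes and 8 of 36 interferon-stimulated genes were lower in M3 (11 and 10 adjusted over the list alone). Of Hox genes 7 of 20 and of epithelial genes 8 of 26 were higher (10 and 9 adjusted over the list alone) in the authors' deposited table. No list passed camera with an estimated correlation in this comparison, where the smallest adjusted p was 0.269, again with little power. The neutrophil chemokine Cxcl5 (chromosome 5, 91188325 to 91190651) fell from 97.8 ± 8.7 to 0.194 ± 0.026 CPM (log2 fold change −8.95 ± 0.19, edgeR adjusted p = 2.06e-14), and the small heat shock protein Hspb8 from 75 ± 2.69 to 0.388 ± 0.052 CPM (−7.58 ± 0.13, 5.80e-15). Ccnd2 rose from 40.2 ± 0.411 to 569.6 ± 7.06 CPM (3.82 ± 0.07, edgeR adjusted p = 5.66e-15), and Hoxa13, a homeobox factor of distal limb and hindgut, from 0.38 ± 0.0344 to 8.02 ± 0.17 CPM (4.38 ± 0.24, 1.53e-09). The authors' deposited table called 543 genes higher and 1072 lower of 17436 tested.

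Genes called higher in M3 held Wipf3, an actin regulator (from 0.0524 ± 0.0265 to 13.9 ± 0.452 CPM), the carboxypeptidase Cpm (from 0.657 ± 0.0238 to 91.3 ± 0.358 CPM), Zfp532 (7.03 ± 0.30 on the log2 scale) and Pou2f3, the tuft-cell transcription factor (from 0.137 ± 0.0927 to 13.3 ± 1.5 CPM). They also held the mast-cell protease Cma1 (6.37 ± 0.30) and the T-box factor Tbx2 (from 0.244 ± 0.107 to 20.6 ± 0.0832 CPM). Some genes called lower had no read in M3, with only lower bounds on their falls, and genes with reads such as Fbln1 may have fallen further. Arhgap32 was at least 323-fold lower, Plcxd3 at least 287-fold, Acss3 at least 265-fold, the defensin Defb1 at least 213.5-fold, the progesterone receptor Pgr at least 191-fold and Lrig3 at least 166.5-fold.

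Of 31 NF-kB and inflammatory genes, 11 fell, 0 rose and 20 did not pass in M3, 11 falling adjusted over the list alone, in the authors' deposited table, with a median of −1.54 at percentile 0 (adjusted p = 0.269 with an estimated correlation). The chemokines Cxcl3 and Cxcl1 fell from 46 ± 0.0918 to 3.63 ± 0.22 CPM and from 32.4 ± 2.49 to 3.21 ± 0.181 CPM. Of 36 interferon-stimulated genes, 8 fell, 1 rose and 27 did not pass (10 fell and 2 rose adjusted over the list alone) in the authors' deposited table, with a median at percentile 0.030 (adjusted p = 0.537 with an estimated correlation). The guanylate-binding protein Gbp2 fell from 7.34 ± 1.11 to 0.511 ± 0.128 CPM and the RNA sensor Ifih1 from 18 ± 1.96 to 3.26 ± 0.306 CPM, while Ifitm1 rose from 2.77 ± 0.139 to 53.9 ± 0.129 CPM. Of 36 NRF2 and glutathione genes 5 fell, 0 rose and 31 did not pass (6 fell adjusted over the list alone) in the authors' deposited table (adjusted p = 0.537 with an estimated correlation). Gsta1 and Gsta2, near-identical glutathione transferases that can share reads, fell from 33.5 ± 0.509 to 3.23 ± 0.0431 CPM and from 19.6 ± 1.58 to 2.24 ± 0.287 CPM, and Gstp1 fell from 138 ± 16.3 to 44.6 ± 0.476 CPM. Of 29 lipid metabolism genes 5 fell and 2 rose (8 and 2 adjusted over the list alone) in the authors' deposited table (adjusted p = 0.537 with an estimated correlation). The desaturase Fads2 fell from 56.6 ± 4.61 to 20.7 ± 0.665 CPM. Of 26 YAP/TAZ targets 4 fell and 1 rose (5 and 1 adjusted over the list alone) in the authors' deposited table (adjusted p = 0.537 with an estimated correlation). The ectonucleotidase Nt5e fell from 57.8 ± 3.01 to 3.42 ± 0.518 CPM.

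Of 33 collagen and matrix genes 11 fell, 2 rose and 20 did not pass (13 and 5 adjusted over the list alone) in the authors' deposited table, with a median of −0.56 at percentile 0 (adjusted p = 0.744 with an estimated correlation). Col3a1 fell to 0.776 ± 0.0542 CPM, whereas the proteoglycan versican (Vcan) rose from 11.5 ± 0.907 to 153 ± 4.6 CPM. Of 24 mesenchymal genes 7 fell and 0 rose (9 and 1 adjusted over the list alone) in the authors' deposited table (adjusted p = 0.537 with an estimated correlation). Among them was Zeb1, a repressor of epithelial genes, from 72.4 ± 1.13 to 30.4 ± 0.794 CPM. Of 26 matrix proteases and inhibitors 6 fell and 1 rose (7 and 1 adjusted over the list alone) in the authors' deposited table (adjusted p = 0.537 with an estimated correlation). Serpine1 fell from 179.5 ± 26.3 to 12.6 ± 0.819 CPM. Of 50 growth factors and ligands 4 rose and 10 fell, 4 and 10 adjusted over the list alone, in the authors' deposited table (adjusted p = 0.537 with an estimated correlation). Wnt5a fell to 0.211 ± 0.0985 CPM and Wnt10a rose from 12.7 ± 1.07 to 79.6 ± 2.17 CPM. Of 25 drug-metabolism genes 5 fell and 1 rose (5 and 2 adjusted over the list alone) in the authors' deposited table (adjusted p = 0.537 with an estimated correlation). The cytochrome P450 Cyp4b1 fell from 25 ± 1.81 to 5.62 ± 0.242 CPM.

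Of 20 tested Hox genes 7 rose, 0 fell and 13 did not pass (10 rose adjusted over the list alone) in the authors' deposited table, with a median of 2.89 at percentile 100 (adjusted p = 0.269 with an estimated correlation). Besides Hoxa13, Hoxb3 rose from 0.224 ± 0.0649 to 4.95 ± 0.944 CPM and Hoxb8 from 0.0178 ± 0.0252 to 1.69 ± 0.209 CPM. Of 26 epithelial genes 8 rose, 3 fell and 15 did not pass (9 and 3 adjusted over the list alone) in the authors' deposited table, with a median of 0.57 at percentile 100 (adjusted p = 0.537 with an estimated correlation). Dsp rose to 163 ± 5.93 CPM and ladinin 1 (Lad1), a basement membrane protein, from 59.8 ± 1.96 to 296 ± 0.872 CPM, whereas Cldn4 fell to 0.512 ± 0.177. Of 35 G1/S genes 6 rose and 0 fell (7 rose adjusted over the list alone) in the authors' deposited table, with a median of 0.49 at percentile 100 (adjusted p = 0.537 with an estimated correlation), and edgeR called 28 higher and 2 lower. The replication helicase subunits Mcm6 and Mcm3 rose from 88.4 ± 3.67 to 246 ± 5.02 CPM and from 64.5 ± 5.79 to 172 ± 3.67 CPM. Of 25 let-7 targets 4 rose and 0 fell in M3 in the authors' deposited table (4 and 1 adjusted over the list alone), with a median of 0.01 at percentile 46.3 (adjusted p = 0.659 with an estimated correlation). The lists of miR-200, miR-34 and miR-17-92 targets had medians inside the central 95% in M3 (percentiles 40, 17.3 and 37.5) in the authors' deposited table. Of their 16, 15 and 16 genes 1, 1 and 1 rose and 3, 2 and 1 fell in the authors' deposited table (1, 1 and 2 rose and 3, 2 and 1 fell adjusted over the list alone), with adjusted p = 0.998, 0.888 and 0.911 with an estimated correlation. Of 34 G2/M genes 0 were called in the authors' deposited table, also adjusted over the list alone, and 11 rose and 9 fell by edgeR. Of 35 DNA repair genes 4 rose and 0 fell in the authors' deposited table, 4 rising adjusted over the list alone (adjusted p = 0.301 with an estimated correlation). The mismatch repair protein Msh2 rose from 64.3 ± 1.62 to 131 ± 2.55 CPM.

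In M3, 21 of 54 lists had medians outside the central 95%, 7 above and 14 below, and with a preset correlation of 0.05 the NF-kB, G1/S and Hox lists passed. None of these did with an estimated correlation (adjusted p = 0.269, 0.537 and 0.269). EdgeR called 9163 genes in M3 (4510 higher, 4653 lower), and 1742 against a change of 2-fold. With Bonferroni adjustment 720 passed in M3 in the authors' deposited table.

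**Figure D3:**
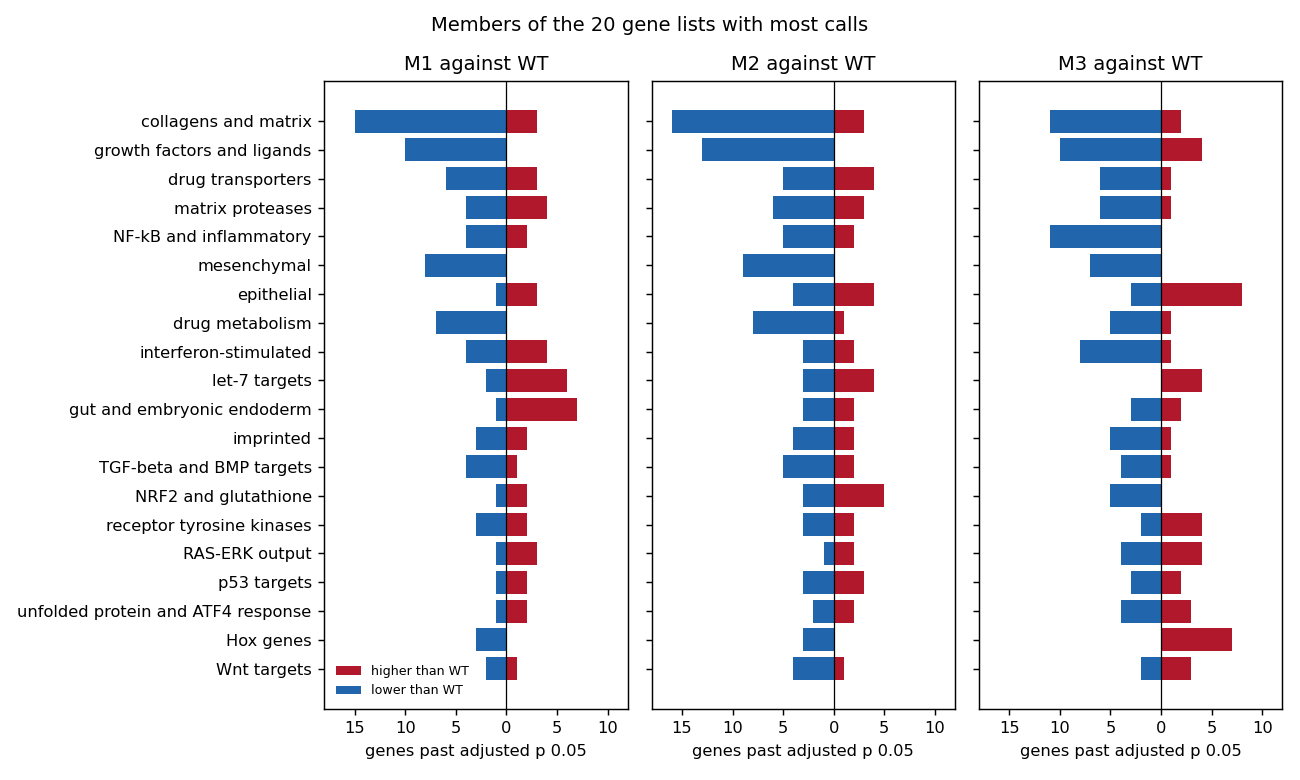
Number of members past an adjusted p of 0.05 in the authors' deposited tables, higher than WT (right) and lower than WT (left), for the 20 lists with most calls in the 3 comparisons. Collagens and matrix had 15, 16 and 11 members lower in M1, M2 and M3, and the Hox genes had 7 higher in M3.

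The lines were then compared with each other through WT. The authors' deposited tables called 996 genes in the same direction in both, 219 higher and 777 lower, where independent lists of the same sizes would share 84.6, and called 18 in opposite directions. Apoc2, an apolipoprotein, rose from 7.69 ± 0.808 CPM in WT to 986.5 ± 76.9 in M1 and 309.7 ± 8.92 in M2. The X-inactivation transcript Xist fell from 1011 ± 97.4 CPM in WT to 2.63 ± 1.77 in M1 and 2.18 ± 1.46 in M2, and stood at 2833 ± 227 in M3. The difference between the M1 and M2 fold changes passed a z test for 204 genes in the authors' deposited tables (140 above in M1, 64 above in M2, of 14581 tested). That test gives no credit for the shared WT, and 553 passed in the authors' deposited tables with the shared part of the error removed and 8351 by edgeR on the recovered reads. For every pair of lines the z test left out genes with no read in WT or in either line, so strong differences can be missing from it. Mxra8, a matrix remodelling protein, was at 0.090 ± 0.0746 CPM in M1 and 49.3 ± 0.198 in M2 against 15.9 ± 2.81 in WT, and the collagen chaperone Serpinh1 at 357.5 ± 37.7 and 5.07 ± 0.611 against 84.7 ± 0.0202. Egln3, a prolyl hydroxylase of hypoxia-inducible factors, was at 0.398 ± 0.194 CPM in M1 and 127 ± 0.182 in M2, and Cyp3a13, a cytochrome P450, at 221 ± 20.2 and 6.17 ± 0.509. As groups, camera with a preset correlation of 0.01 put the G1/S, G2/M and DNA repair lists lower in M1 than in M2 (adjusted p = 0.306 with an estimated correlation for each) and the gut and lipid lists higher (adjusted p = 0.61 with an estimated correlation for each).

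The authors' deposited tables called 656 genes in the same direction in M1 and M3 (87 higher, 569 lower, where independent lists would share 76.5) and 80 in opposite directions. In M2 and M3 the authors' deposited tables called 672 (65 higher, 607 lower, where independent lists would share 93.5), with 108 opposite. The fold changes differed by the z test for 708 genes between M1 and M3 (328 above in M1, 380 above in M3) and for 889 between M2 and M3 (368 above in M2, 521 above in M3) in the authors' deposited tables. With the shared WT part of the error removed 1541 and 2021 passed in the authors' deposited tables, and by edgeR 9899 and 9882. The zinc finger gene Zfp503 was at 50.9 ± 3.34 CPM in WT and 113.5 ± 0.0413 in M3, but at 0.073 ± 0.00228 in M1 and 0.10 ± 0.046 in M2. The glycosyltransferase Galnt18 was at 42 ± 1.33 and 134 ± 2.89 against 0.090 ± 0.0746 and 0.369 ± 0.194. Map2 was at 17.9 ± 0.345 CPM in WT and 36.1 ± 0.104 in M3, at 0.0169 ± 0.0239 in M2 and without a read in M1. By camera with a preset correlation of 0.01, NF-kB and inflammatory genes lay lower in M3 than in M1 (adjusted p = 0.301 with an estimated correlation) and in M2 (adjusted p = 0.339 with an estimated correlation). By the same test Hox genes lay higher in M3 than in M1 (adjusted p = 0.301 with an estimated correlation) and in M2 (adjusted p = 0.339 with an estimated correlation). G2/M genes lay higher in M2 than in M3 (adjusted p = 0.657 with an estimated correlation).

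All 3 comparisons share the WT libraries, so their chance values are linked. With unchanged simulated lines against the same WT, the number of shared calls was 0 in each pair with the spread within lines. It was at most 1 with the spread that the authors' p-values imply. The simulated lines had a mean of only 0.0733 and 1.44 calls each at these spreads, so hardly any could be shared. The simulation covers the error of the WT libraries, and cannot tell whether the WT line itself is the one that differs. The Pearson correlation of fold changes across genes, in the authors' deposited tables, was 0.785 for M1 and M2, 0.513 for M1 and M3 and 0.532 for M2 and M3, against simulated values of 0.50, 0.496 and 0.499. With the spread the authors' p-values imply, the simulated values were 0.467, 0.511 and 0.528, near the observed ones for M3. Unchanged lines against a shared WT thus reach about these values at either spread, so the Pearson correlation cannot tell shared change from shared WT for M3. The covariance was 1.63, 0.871 and 0.973 in the authors' deposited tables, against 0.0118, 0.0117 and 0.0117 simulated, differences of 1.62, 0.86 and 0.961. With the spread the authors' p-values imply, the differences were 1.47, 0.706 and 0.807. Part of the excess over independent lists may come from the shared WT, whose 2 libraries are too few to split.

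All 3 mutant lines differed from WT in the same direction for 536 genes, 40 higher and 496 lower, in the authors' deposited tables, where independent lists would share 4.96. With a mean of at least 100 normalised counts 307 did so in the authors' deposited tables. By edgeR 3665 did so, and shared calls in a pair came to 6850, 4919 and 4721. The value of 4.96 does not apply to these, since edgeR called 10001, 9882 and 9163 of 13803 genes in M1, M2 and M3. Lists that long share many genes by chance, and that number was not computed. Dsp rose by 4.33 ± 0.08, 4.83 ± 0.08 and 4.62 ± 0.08 on the log2 scale in M1, M2 and M3. The intermediate filament nestin (Nes) rose from 31.7 ± 1.53 CPM to 697 ± 36.2, 662 ± 6.06 and 318 ± 0.295. The kindlin Fermt1 rose from 1.54 ± 0.113 to 27 ± 1.95, 43.3 ± 0.088 and 77.5 ± 0.811, and Gprc5c, a receptor, from 2.0 ± 0.364 to 161.5 ± 6.08, 48.6 ± 3.19 and 74.9 ± 1.2. The ribonuclease Rnase4 rose from 4.39 ± 0.322 to 155 ± 10.3, 40.9 ± 1.49 and 50.3 ± 1.06 CPM, and Apoc2 to 17.5 ± 0.422 CPM in M3. Among the shared falls, the choline transporter Slc5a7 went from 198 ± 2.15 CPM to 0.0178 ± 0.0252, 0.267 ± 0.0437 and 0.846 ± 0.0451. The alpha-catenin Ctnna2 went from 72.2 ± 1.26 to 0.0178 ± 0.0252, 0.10 ± 0.046 and 0.405 ± 0.172, and the sodium-calcium exchanger Slc8a1 from 84 ± 0.954 to 0.0186 ± 0.0264, 0.266 ± 0.233 and 0.229 ± 0.0236. The protocadherin Pcdh17 fell from 99.3 ± 1.0 to 0.0916 ± 0.0286, 0.183 ± 0.116 and 0.371 ± 0.177 CPM. Its relative Pcdh10 went from 38.6 ± 2.3 to 0.0186 ± 0.0264, 0.117 ± 0.0221 and 0.0531 ± 0.0751, and the orphan receptor Gpr149 from 28.9 ± 0.174 to 0.0186 ± 0.0264, 0.0675 ± 0.0955 and 0.0351 ± 0.0497.

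By list, 7 of 33 collagen and matrix genes fell in all 3 lines in the authors' deposited tables (Col3a1, Col5a2, Col6a2, Lama3, Fbln1, Bgn and Dcn). So did 4 of 23 mesenchymal genes (Twist2, Fbn1, Tcf4 and Col5a2) and 4 of 31 inflammatory genes, all chemokines (Cxcl3, Cxcl5, Ccl7 and Cxcl12). The same held for 3 of 14 fibroblast genes (Dcn, Col3a1 and Cspg4) and 2 of 11 endothelial genes (Tek and Plvap). In M3 0 fibroblast genes rose and 3 fell (adjusted p = 0.629 with an estimated correlation). Endothelial genes also rose, 2, 0 and 2 of them in M1, M2 and M3, with 2 falling in each (adjusted p = 0.858, 0.541 and 0.621 with an estimated correlation). Of 23 drug transporters 5 fell in all 3 lines in the authors' deposited tables, namely Abca1, Slc47a1 and the multidrug transporters Abcb1a, Abcb1b and Abcb4, close relatives that can share reads. The members of all these lists were named after their values were seen. Of 31 NF-kB and inflammatory genes, 2 rose and 4 fell in M1 and 2 rose and 5 fell in M2 in the authors' deposited tables (3 and 4, and 3 and 7, adjusted over the list alone). Their medians lay at percentiles 21.7 and 49.8 (adjusted p = 0.992 and 0.881 with an estimated correlation). In all, 3, 4 and 1 drug transporters rose and 6, 5 and 6 fell in M1, M2 and M3 in the authors' deposited tables (4, 4 and 2 rose and 6, 6 and 6 fell adjusted over the list alone), with medians inside the central 95% (percentiles 78.6, 46.2 and 9.5). With an estimated correlation that list had adjusted p = 0.858, 0.981 and 0.793. Abcb1a fell from 706 ± 2.0 CPM to 164 ± 1.77, 69.9 ± 1.08 and 227 ± 1.64. Eda2r, a receptor of the ectodysplasin family and a p53 target, fell from 76.7 ± 4.44 CPM to 1.37 ± 0.43, 0.201 ± 0.00266 and 1.62 ± 0.0407, and Grb10 from 63.4 ± 3.94 to 0.257 ± 0.111, 0.134 ± 0.00178 and 0.123 ± 0.0741. Medians outside the central 95% lay below in all 3 lines for 7 lists (collagens and matrix, mesenchymal, matrix proteases, basal and squamous, growth factors and ligands, TGF-beta and BMP targets, drug metabolism) and above for replication-dependent histones, whose messages largely lack poly(A) tails. None of these 7 lists passed with an estimated correlation in any line (adjusted p = 0.504 to 0.827). Of 33 histone genes 2, 0 and 5 rose in M1, M2 and M3 in the authors' deposited tables, with 2, 0 and 6 adjusted over the list alone. The histone list had adjusted p = 0.827 with an estimated correlation in M1, adjusted p = 0.856 with an estimated correlation in M2 and adjusted p = 0.621 with an estimated correlation in M3.

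Genes of whole chromosomes shifted together. On mm9 coordinates, chromosome 18 genes had a median log2 fold change minus that of the other chromosomes of −0.33 in M1, −0.59 in M2 and −0.56 in M3 in the authors' deposited tables. In M3, 9.57% of its genes lay above the median of the rest in the authors' deposited table. Chromosome 5 lay at −0.24, −0.48 and −0.38 and chromosome 14 at 0.49, 0.31 and 0.34 relative to the rest in the authors' deposited tables. Chromosome 1 stood at 0.58 in M3 and −0.17 in M2, chromosome 8 at 0.45 in M2 and chromosome 7 at 0.52 in M3 in the authors' deposited tables. Of 60 medians, 46 lay outside the central 95% of random gene sets matched on expression.

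**Figure D4:**
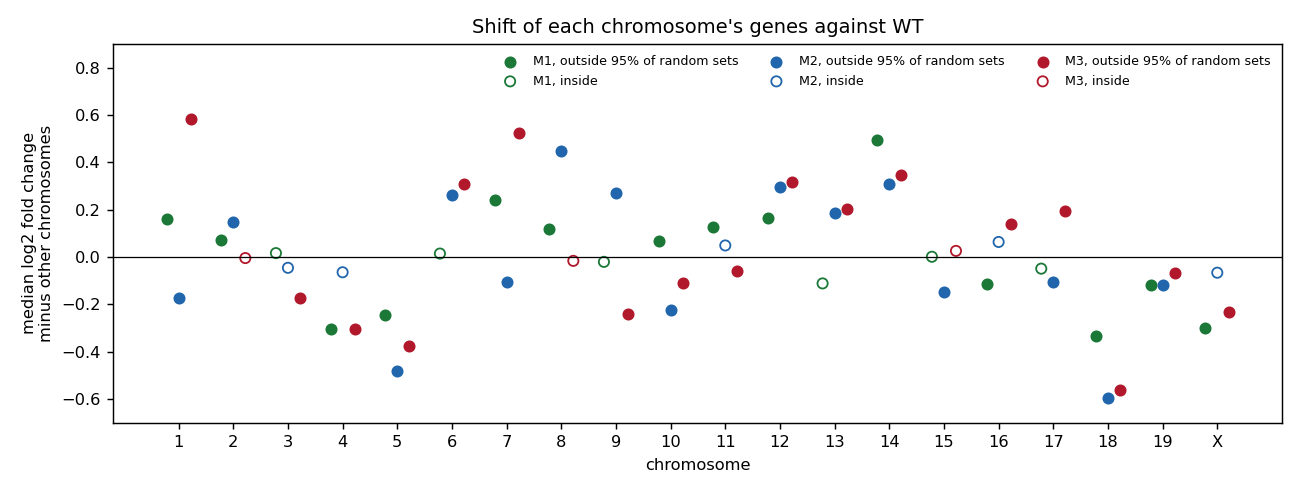
Median log2 fold change of the genes of each chromosome minus that of all other chromosomes (log2 units), in the authors' deposited tables, for M1, M2 and M3 against WT. Filled points lie outside the central 95% of 10000 random gene sets, 46 of 60. Chromosome 18 lies below 0 and chromosome 14 above 0 in all 3 comparisons, which share the same WT line and so may reflect WT.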

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

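The tests of the spread behind the authors' tables, of X reactivation and of Tsix reads were chosen only after the result was seen.

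The genes below were called in opposite directions against WT in a pair of mutant lines in the authors' deposited tables, and the difference of their log2 fold changes passed the z test. Between M1 and M2 the difference (M1 minus M2) was −9.08 for Mxra8, −8.30 for Egln3, 6.16 for Serpinh1 and 5.18 for Cyp3a13 in the authors' deposited tables (adjusted p = 7.23e-18, 4.23e-18, 1.14e-14 and 2.96e-09). Between M1 and M3 the difference (M1 minus M3) was −10.61 for Zfp503, −10.60 for Tsix, −10.54 for Galnt18 and −10.07 for Xist in the authors' deposited tables (adjusted p = 9.80e-27, 2.61e-28, 2.41e-27 and 9.89e-32). Between M2 and M3 the difference (M2 minus M3) was −11.08 for Map2, −10.52 for Tsix, −10.36 for Xist and −10.17 for Zfp503 in the authors' deposited tables (adjusted p = 2.53e-28, 1.09e-45, 1.48e-60 and 2.97e-41). Map2 had 1 read over the M2 libraries, so its difference is imprecise. Genes with no read in WT or in a line of the pair were not in the z test, so Map2 was not tested between M1 and M3.

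Xist, the long RNA that silences an X chromosome, had 32020 and 26465 reads in the WT libraries and 85237 and 75498 in M3, but 109 and 37 in M1 and 97 and 34 in M2. A silenced X chromosome that became active would raise X-linked genes together. Their medians relative to the other chromosomes were −0.30 and −0.07 in the authors' deposited tables for M1 and M2. These values argue against reactivation only if the number of X chromosomes was unchanged, which is not known. Loss of the X chromosome that carried the active Xist gene stays open and cannot be told apart from other causes, since only 4 genes that escape X inactivation were at hand. Relative to other X-linked genes their median difference from M3 was −0.40 in M1 and −0.63 in M2, with 3 of them lower in both lines, but against WT the medians were 0.34 in M1 and 0.12 in M2. Tsix, antisense to Xist, had 5.82% of the Xist reads in WT and 5.96% in M3, a log2 difference of 0.03, consistent with Xist reads counted for Tsix, and the counting strand is not given in the sources used here.

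Genes of whole chromosomes shifted together, with 46 of 60 medians outside the central 95%. With the trend against GC content and transcript length removed (values for 97% of genes) 47 lay outside, no median moving by more than 0.08, and with every called gene left out 47 did, which argues against either as the whole cause. Gain or loss of whole chromosomes, in WT or in the mutants, may account for some shifts. The proximal and distal parts lay on the same side for 45 of 46 shifted chromosomes, but differed beyond random gene orders in 13 (28.3%), between the bounds set in advance, so this stays open.

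The authors' deposited tables call several times fewer genes than edgeR on the recovered reads. P-values recomputed with the spread between the libraries of a line lay a median of 5.49 to 8.51 from the deposited ones on the log10 scale, which argues against that spread as their basis. The dispersion that the deposited p-values imply lay on 1 curve of the mean in each table (R squared 0.9875 to 0.9996), consistent with a test that left each gene's own spread out. Taking all 4 libraries as 1 condition gave p-values a median of 0.0435 from the deposited ones for M1, so it may account for that table, but 0.173 and 0.202 for M2 and M3, which argues against it there. No biological explanation of these counts was tested.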

How the results depend on the processing

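Every test on the recovered reads was added after the data were seen, apart from the scaling, tool and left-out libraries, which were set before. Values are in the order M1, M2 and M3, or M1 with M2, M1 with M3 and M2 with M3. No single gene among those named was reversed under any alternative run. The other thresholds reuse the same fold change, so they could not reverse one. No paired analysis was possible because the labels give 1 sample per line, and the numbers 1 and 2 of the recovered libraries only order them by size factor and pair nothing. Genes called against WT came to 617, 769 and 720 with the stricter Bonferroni adjustment and to 10001, 9882 and 9163 with edgeR. With edgeR on only the 4 libraries compared they came to 9217, 10445 and 9678. With a mean of at least 100 normalised counts, and so fewer genes, 887 were called in M1 and 307 in all 3 lines. Tested against a change of 2-fold, a stricter question, edgeR called 2540, 2320 and 1742 against WT and 1170, 2287 and 2163 between lines. Gene lists came to 12, 12 and 12 by cameraPR with correlation 0.01 and 4, 6 and 3 with 0.05, where a larger correlation widens the error. By camera on the recovered reads they came to 10, 5 and 8 with correlation 0.01 and 0, 0 and 0 with an estimated one. At an unadjusted p under 0.05 the last came to 4, 4 and 4 lists. Differences between lines came to 553, 1541 and 2021 with the shared WT part of the error removed, which makes the error smaller, and 8351, 9899 and 9882 by edgeR. Shared calls by edgeR came to 6850, 4919 and 4721, and 3665 in all 3 lines. Lists as long as those of edgeR share many genes by chance, and that number was not computed. Tests of why edgeR calls more genes than the authors' deposited tables are given with the results. For camera against percentiles the cause was not tested, but camera with an estimated correlation had only 4 residual degrees of freedom. For Hox genes in M3 the estimated correlation was −0.0105. Their unadjusted camera p was nonetheless 0.00962 with it, against 9.97e-06 with correlation 0.01. Leaving out each library in turn, where a lone library is assumed to vary like the other lines, gave 9041 to 10243, 8732 to 8922 and 8038 to 8299 calls against WT and 6782 to 8712, 8923 to 10082 and 8763 to 8899 between lines. Among the calls of the authors' deposited tables that edgeR tested, 0 turned direction. The authors' own test was not rerun, so this does not show how their calls depend on 1 library. Without M1 library 1 the log2 fold change of Kras in M1 (0.20) newly passed, and without WT library 1 that of Dicer1 in M3 (−0.19) did not pass. For single genes in the authors' deposited tables, each gene counted once per comparison and setting (thresholds of 0.01 and 0.1, and edgeR). Of these values, 1155 kept their side of the threshold, 38 missed a threshold of 0.01 and 4 passed newly by edgeR. A called gene always passes 0.1, so part of this was fixed in advance. RLE scaling in place of TMM moved the median of all genes most in M1, by −0.0338 on the log2 scale. Depth limits what can be said of genes at 3 reads or fewer over a line.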

Other observations

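The edgeR values were computed by a test chosen after the data were seen, while lists and the rule for naming genes were set before. Among receptor tyrosine kinases, Fgfr1, a fibroblast growth factor receptor, rose from 5.97 ± 0.767 to 76.1 ± 2.72 CPM in M3. It fell to 0.676 ± 0.0984 CPM in M1 and 0.417 ± 0.16 in M2 (edgeR log2 fold changes −3.13 ± 0.20 and −3.82 ± 0.22). Flt1, a VEGF receptor, rose from 6.51 ± 0.0452 to 139 ± 6.12 CPM in M3. Of 35 receptor tyrosine kinases 4 rose and 2 fell in M3 in the authors' deposited table, 4 and 2 adjusted over the list alone (adjusted p = 0.738 with an estimated correlation). The secreted mucins Muc5b and Muc5ac rose from 9.18 ± 0.702 to 103 ± 18 CPM and from 0.345 ± 0.0848 to 10.2 ± 0.531 CPM in M3, while Muc5b fell to 1.7 ± 0.182 CPM in M1 and Sprr1a fell from 1149 ± 99.1 to 169.8 ± 8.41 CPM in M3 and rose to 7248 ± 535.5 CPM in M1. Of 11 club and secretory genes 2 rose and 2 fell in M3 in the authors' deposited table, 2 and 2 adjusted over the list alone (adjusted p = 0.888 with an estimated correlation). The integrin Itga2 rose from 6.17 ± 0.474 to 140.4 ± 6.06 CPM in M1 and to 115 ± 0.0327 in M2. The imprinted gene Peg10 rose from 9.2 ± 0.229 to 424 ± 16.8 CPM in M1, and H19 from 0.122 ± 0.0291 to 4.92 ± 0.645 CPM in M3. Of 25 imprinted genes 2 rose and 3 fell in M1, and of 24 in M3 1 rose and 5 fell, in the authors' deposited tables. Adjusted over the list alone, 2 rose and 3 fell in M1 and 1 rose and 6 fell in M3. The medians lay at percentiles 82 and 1.32 (adjusted p = 0.971 and 0.537 with an estimated correlation).

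Cyclin D1 (Ccnd1) rose from 319 ± 15.3 to 1132 ± 13.5 CPM in M3 and Mycn from 2.62 ± 0.0754 to 21.4 ± 0.502 CPM, while Mycn fell to 0.167 ± 0.0451 CPM in M2. Of 36 NRF2 and glutathione genes 5 rose and 3 fell in M2 in the authors' deposited table, 7 and 3 adjusted over the list alone (adjusted p = 0.661 with an estimated correlation). Among them was the glutathione transferase Gstm2, which rose from 19.3 ± 1.52 to 83.8 ± 0.261 CPM. Calls in 1 line and not in the others came to 300 genes in M1, 537 in M2 and 697 in M3 in the authors' deposited tables, which does not show that they differ between lines.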
